A study of Rattus norvegicus with 12 samples.

How the data were processed

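Total RNA of the OLN cells was isolated with RNeasy columns and labelled as biotinylated cRNA by the standard Affymetrix protocol, per the labels' protocols. Signal intensities of 1 array per sample were made with MAS5, per the submitters' processing notes, whose version is not given in the sources used here. The deposited intensity values are linear MAS5 signals of 31096 probe sets, and their 2% trimmed mean was 150.1 on each of the 12 arrays, so the authors scaled the arrays to a common level. Per the file headers, the authors also deposited detection calls (present, marginal, absent) per array, and signal log ratios (log2) with change calls for pairs of arrays, the array named first over the second. A second deposited table holds the same intensities rounded to whole numbers. It differed by at most 0.5 signal units and served only to check which column belongs to which sample, and 3 of its probe sets are not analysed here.

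Samples were grouped by title into mock and p25alpha cells at 8, 12 and 16 h, with the experiment number of the title as the replicate. Signals were floored at 0.1 (16 tested values lay at the floor) and log2 was taken. Probe sets called present on at least 2 of 12 arrays were tested, and 57 Affymetrix control probe sets were left out, which kept 19248, or 61.9%. MAS5 scaling by a trimmed mean leaves differences in signal distribution between arrays, and low signals are noisy on the log scale, so folds of dim probe sets are imprecise. Where a probe set was absent on all arrays of a group, the fold rests on signals called absent. It sets the brighter group's mean log2 signal against that of the dim group. On each dim array the higher of the probe set's own signal and the array's lowest signal called present was used. That lowest signal was only 2.7 to 6.4, so such a fold is close to the fitted one and is not a guaranteed minimum.

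Gene symbols come from the deposited annotation, updated by symbol, synonym or gene number through a RefSeq gene table of assembly GRCr8, which was used for names only. A single symbol was found for 20190 probe sets, several for 347 and none for 10559, and 1330 kept the symbol of the file. No coordinates are given, because no genome build is named in the sources used here.

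The main model was limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) over all 12 arrays with 6 group means and 6 residual degrees of freedom, without a block. Contrasts were p25alpha against mock at each time, their mean over the 3 times, a moderated F-test of whether the effect differs between times, and mock cells at 12 and 16 h against 8 h. Adjusted p-values are Benjamini-Hochberg values over all tested probe sets with a threshold of 0.05. The other planned fit has the experiment as a replicate block. The labels number the experiments, and the deviations of same-numbered arrays from their group means correlated at 0.47 to 0.57 in all 15 pairs of groups. The first principal component (42% of the variance) also separated the 6 arrays of each experiment, so the numbers were taken to pair the arrays.

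The rule for named genes, set before the data were examined, took probe sets past the threshold with 1 symbol, the same sign in all pairs and a brighter arm above the median log2 signal of tested probe sets (6.68). It named the 12 largest rises and falls over all times, 6 per single time, and 4 each way for time in mock cells and for time dependence. Where fewer than 3 passed in a direction, the 5 with the smallest p were named as not passing. The 2 to 4 members of each list with the largest change, and Tppp, Fas and Nfkbia, were always to be named. Some genes that the rule names are not reported here. The same rule was applied to the paired fit after the experiment effect had been seen.

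Before the data were examined 18 gene lists with 366 members were fixed, of which 328 had a probe set. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01 on 9148 genes, each by its brightest tested probe set, adjusted over the 17 lists with at least 2 tested members. Camera with an estimated correlation and fry were alternatives.

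Other alternatives were the experiment as a random replicate block, quantile normalization, median centring, no filter on dim probe sets, a filter at the median signal, an offset of 50 before log2, eBayes with trend and robust, only the 4 arrays compared, the mean over a gene's probe sets, and leaving out each array in turn. In the last, a group left with 1 array is assumed to vary like the others. The paired fit under these settings, its version with trend and robust, the actin 3′ over 5′ ratio as a covariate, and the list tests over time were added after seeing the data.

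The code was tested on simulated data with the real means, experiment effects and residual spread of the 19248 probe sets. For the effect over all times, the fit without the block called 0 of 50 probe sets changed by 0.5 on the log2 scale, 8 of 50 changed by 1, 33 of 50 changed by 2 and 42 of 50 changed by 3, with 3 unchanged ones called. The replicate block called 17, 24, 43 and 46 of 50, with 6 unchanged ones called. For the same comparison a simulated list of 20 probe sets shifted by 0.5 was called in both fits and 0 of 50 unchanged lists were. The simulated probe sets varied independently of each other. In the real data the estimated correlation was 0.202 in the NF-kB list and 0.206 in the cholesterol list. The simulation therefore does not show how often unchanged real lists are called with the preset correlation. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.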

Results

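Gene expression was measured in a stably transfected rat oligodendroglial cell line (OLN). The cells were transfected either with an empty vector (mock) or with a plasmid for p25alpha (TPPP), a tubulin-binding protein of oligodendrocytes. RNA was taken 8, 12 and 16 h after transfection in 2 experiments, which gave 12 Affymetrix rat arrays in 6 groups of 2, one array per experiment in each group. The labels do not say whether the experiments used separately grown cultures, so the p-values measure the spread between these arrays, which may be partly technical. Between 49.3% and 55.2% of the 31096 probe sets were called present per array, and 19248 probe sets present on at least 2 of the 12 arrays were tested. The number of arrays, 2 per group, limits the precision. Arrays of one experiment correlated at 0.975 to 0.990 over 12906 probe sets present throughout (correlations across genes within arrays), and arrays of different experiments at 0.916 to 0.953. Because the experiment number paired the arrays, each comparison is given from the fit without and from the fit with the experiment as a block, called the paired fit here. The actin 3′ over 5′ signal ratio, a sign of RNA quality, lay between 2.14 and 3.12 in experiment 1 and between 4.65 and 7.05 in experiment 2. The same ratio of GAPDH did not show this difference, lying between 0.97 and 1.09 in experiment 1 and between 0.90 and 1.03 in experiment 2. The p25alpha array had a higher median signal than its mock array in 6 of 6 pairs (0.11 ± 0.10 on the log2 scale, SD) and fewer present calls in 5 of 6.

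The expressed gene was looked for first. No probe set was found under the symbol Tppp or its synonyms, but 10559 probe sets have no gene name, so it is open whether one of them detects the p25alpha transcript, which was not analysed here.

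The first comparison asked which transcripts differ when p25alpha is expressed in these cells, over all 3 times together. Il6, which encodes interleukin 6, rose 5.3-fold (log2 2.41 ± 0.18 SE, higher in 6 of 6 pairs, limma adjusted p = 0.00582), from a geometric mean signal of 51.2 to 271.3. Egr1, an immediate early transcription factor, rose 5.05-fold (2.34 ± 0.14, 6 of 6 pairs, adjusted p = 0.00138). LOC310926, a gene known only as a hypothetical protein, was not above background on any mock array and was present on all 6 p25alpha arrays. Its 10.3-fold difference (adjusted p = 0.0293) rests on mock signals called absent. With a probe set that has no gene name (log2 2.27, adjusted p = 0.00138), which lies outside the rule for named genes, these were the 4 probe sets past the threshold, and 0 fell. Of the lower transcripts with the smallest p, RGD1561637 was at -0.63 ± 0.13 and Eef2k, a kinase that acts on elongation factor 2, at -0.59 ± 0.14, and neither passed. The other tested probe sets measured 0.05 and -0.48 for RGD1561637 and 0.02, -0.25 and -0.42 for Eef2k. At an unadjusted p under 0.05 there were 794 probe sets, where chance alone would give 962 if the p-values were calibrated. This fit leaves the difference between the experiments in its residual spread, which makes its p-values too large, so 794 is not read as below chance. The call of LOC310926 was lost without any single array other than the p25alpha arrays at 16 h (adjusted p from 0.0826 to 0.2), without a filter on dim probe sets (adjusted p = 0.0637) and with an offset of 50 (adjusted p = 0.0547), while Il6 and Egr1 were called without each of the 12 arrays.

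In the paired fit 46 probe sets passed, 40 higher and 6 lower in p25alpha cells. An unadjusted p under 0.05 was found for 2693, where chance alone would give 962. Naming genes from this fit was decided after the experiment effect had been seen. The chemokines Cxcl1 and Ccl2, which attract neutrophils and monocytes, rose 8.89-fold (log2 3.15 ± 0.18 SE, adjusted p = 0.00115) and 5.28-fold (2.40 ± 0.15, adjusted p = 0.0026), each in 6 of 6 pairs. Without the block their adjusted p were 0.0881 and 0.247. Gadd45b, a stress-induced growth arrest gene, rose 3.85-fold, and Txnip, which encodes an inhibitor of thioredoxin, also rose. It was present on 1 of 6 mock and 6 of 6 p25alpha arrays, so its fitted 3.68-fold rests mostly on mock signals called absent. Nfkbia, the inhibitor and target gene of NF-kB, rose 2.86-fold (1.52 ± 0.12, adjusted p = 0.00814 paired and 0.47 without the block). Myc rose 2.10-fold, Ppp1r15a, a subunit of the phosphatase that acts on eIF2alpha, rose 2.05-fold, and the pro-apoptotic gene Bbc3 rose 1.99-fold. The replication helicase gene Mcm6 fell by 0.62 ± 0.07 and Arfgap3, a regulator of Golgi transport, fell by 0.57 ± 0.07 on the log2 scale, both lower in 6 of 6 pairs. Snrnp200 at -0.50 and Glmn at -0.63 did not pass, and another Glmn probe set was at 0.11. One Fkbp2 probe set rose 7.53-fold, whereas the other Fkbp2 probe sets measured -0.07 ± 0.08 and 0.12 ± 0.09, so no change of the Fkbp2 transcript can be read from it. Without p25alpha 16 h replicate 2 the paired fit called 33, and without any other single array it called 12 to 27, with 12 when p25alpha 16 h replicate 1 was left out.

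**Figure D1:**
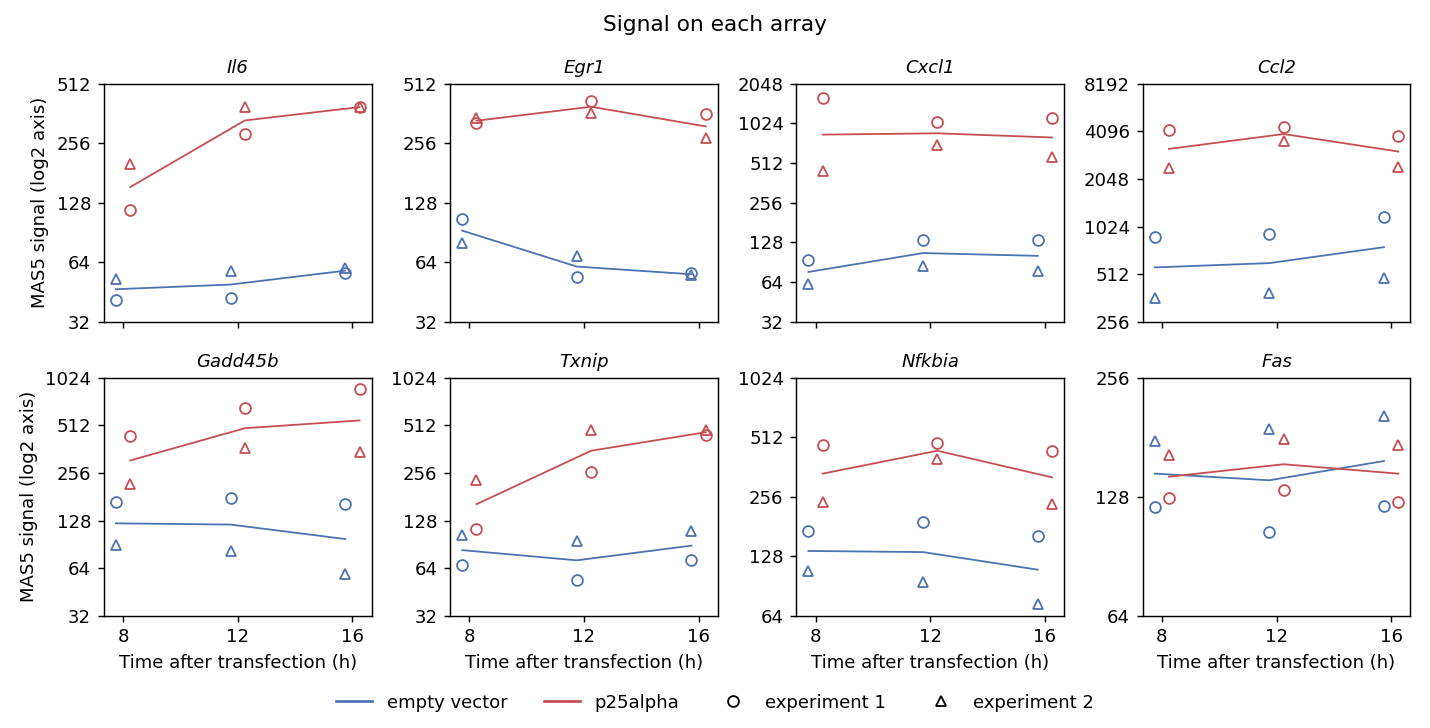
MAS5 signal (log2 axis) of 8 genes on each of the 12 arrays against time after transfection (h), with mock in blue, p25alpha in red, circles for experiment 1, triangles for experiment 2 and lines through the geometric mean of each group. Il6, Egr1, Cxcl1, Ccl2, Gadd45b, Txnip and Nfkbia were higher in p25alpha cells in 6 of 6 pairs, and Fas (0.00 ± 0.23 on the log2 scale over all times) was not separated.

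Gene lists fixed before the data were examined were tested with camera, and 5 of 17 lists were shifted upwards over all times. Of the 20 immediate early genes measured, 18 were higher in p25alpha cells, with a median of 0.43 on the log2 scale (adjusted p = 2.38e-15, and adjusted p = 0.0327 with an estimated correlation). With an estimated correlation in the paired fit the call was lost (adjusted p = 0.0817). In the paired fit 5 of them rose by the adjustment over all genes and 12 when adjusted over the list alone, and 8 did not pass. Egr1, Myc, Fos (2.79-fold), Btg2 (2.11-fold) and Ier3 (1.80-fold) were the 5, Btg2 being dim (present on 1 mock and 2 p25alpha arrays) and another Btg2 probe set not passing (0.83, adjusted p = 0.17). Junb (log2 1.19 ± 0.16) passed over the list alone, and Jun was at -0.09 ± 0.08. Without the block 1 rose over all genes and 9 adjusted over the list alone. All 16 NF-kB targets measured were higher, with a median of 0.49 (adjusted p = 6.02e-12, adjusted p = 0.0503 with an estimated correlation). Of these, Cxcl1, Il6, Ccl2 and Nfkbia rose in the paired fit by the adjustment over all genes. The same 4 with Csf1 (0.65 ± 0.11), Irf1 (0.62 ± 0.11) and Nfkbib (0.35 ± 0.11) made 7 when adjusted over the list alone, and 9 did not pass. Without the block the counts were 1 and 6. Sod2 at 0.02 ± 0.08 and Icam1 at 0.13 ± 0.19 were among those that did not.

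Smaller shifts of 3 further lists were past the threshold with the preset correlation and not with an estimated one. The oxidative stress list had a median of 0.18 over 17 genes (adjusted p = 0.000666, adjusted p = 0.0503 with an estimated correlation). Srxn1, which reduces oxidised peroxiredoxins, rose 1.61-fold in the paired fit over all genes by one probe set, another being at 0.50 (adjusted p = 0.183). With Hmox1 (1.72-fold) and Ftl1 (1.26-fold) 3 rose when adjusted over the list alone, and 14 did not pass. The interferon list had a median of 0.17 over 18 genes (adjusted p = 0.00907, adjusted p = 0.0969 with an estimated correlation). Of its members 0 passed over all genes, and 2 rose when adjusted over the list alone, Bst2 (log2 1.37 ± 0.27, present on 1 mock and 3 p25alpha arrays) and Cxcl10 (0.66 ± 0.10). The p53 target list had a median of 0.05 and a mean of 0.23 over 18 genes (adjusted p = 0.029, adjusted p = 0.0998 with an estimated correlation). Its Btg2 and Bbc3 rose in the paired fit over all genes, joined by Gadd45a (0.73 ± 0.13) and Mdm2 (0.70 ± 0.11) when adjusted over the list alone, which made 4 of 18. A second Mdm2 probe set passed over all genes (0.91, adjusted p = 0.0499). Without the block 0 members of these 3 lists passed over all genes, and 0, 0 and 3 when adjusted over the list alone. The p53 list was no longer called without mock 8 h replicate 2, p25alpha 8 h replicate 1, p25alpha 12 h replicate 1, p25alpha 16 h replicate 1 or replicate 1 of the mock arrays at 12 or 16 h (adjusted p from 0.0585 to 0.114), and after quantile normalization (adjusted p = 0.0769). The interferon list was no longer called without mock 12 h replicate 1 (adjusted p = 0.0585) or p25alpha 16 h replicate 2 (adjusted p = 0.104). With an estimated correlation in the paired fit 0 of the 17 lists passed, the adjusted p being 0.0993 for the NF-kB targets.

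The remaining 12 lists were not called over all times by camera with the preset correlation in either fit, which does not show that they were unchanged. In the death receptor and apoptosis list 16 of 23 genes were higher and 0 passed in either fit, over all genes or adjusted over the list alone. Fas, a death receptor, measured 0.00 ± 0.23 by its brighter probe set and 0.18 ± 0.20 by another, and a further Fas probe set was present on 0 of 12 arrays. Its ligand gene Faslg measured 0.76 ± 0.18 in the paired fit (adjusted p = 0.174), with present calls on 3 mock and 6 p25alpha arrays. The unfolded protein response list had a median of -0.07 and a mean of 0.07, with the test pointing downwards (adjusted p = 0.467). Ppp1r15a rose over all genes in the paired fit. When adjusted over the list alone 4 rose and 3 fell, the risers including Ddit3 (log2 1.15 ± 0.16) and Chac1 (0.84 ± 0.16), and the fallers Pdia4 (-0.42 ± 0.12), Xbp1 (-0.37 ± 0.07) and Canx (-0.30 ± 0.07). Another Ddit3 probe set was at 0.51 (adjusted p = 0.163), and other Canx probe sets were at -0.18 and -0.08. Of 24 cell cycle genes 1, Mcm6, fell over all genes in the paired fit, while E2f1 (0.55 ± 0.11) rose and Mcm6, Top2a (-0.40 ± 0.11) and Birc5 (-0.30 ± 0.07) fell when adjusted over the list alone, other Top2a probe sets being at 0.03 and -0.43. The heat shock list had 1 of 16 genes past the threshold adjusted over the list alone in the paired fit. This was Hspa1b, 1.74-fold higher than mock signals that were all called absent. Without the block 0 members of the unfolded protein response, cell cycle and heat shock lists passed, over all genes or adjusted over the list alone. No gene of the cholesterol, glycolysis, autophagy, microtubule or oligodendrocyte lists passed in the paired fit, with medians of -0.07, -0.01, 0.00, -0.06 and -0.05, over all genes or adjusted over the list alone. The members farthest from 0 were Ndrg1 (1.60-fold, set against mock signals all called absent) in the glycolysis list, Mcoln1 (-0.37 ± 0.11) in the autophagy list and Nkx2-2 (-0.38 ± 0.10) in the oligodendrocyte list. In the microtubule list they were Tubb3 (1.97-fold, absent on all mock arrays and present on only 2 p25alpha arrays) and Mapt (-0.81 ± 0.42, present on 1 array of each arm). Lists of markers of other cell types had medians of 0.16 for 8 neuron, -0.04 for 6 astrocyte and -0.27 for 5 fibroblast and smooth muscle genes, and Acta2 (-1.12 ± 0.31) fell when adjusted over its list alone in both fits. The microglia list had 1 tested member and was not tested. At single times the median, mean and test direction differed in sign only in lists that were not called, among them the p53 targets at 12 h (-0.04 and 0.17), the heat shock list at 8 h (0.05 and -0.07) and the unfolded protein response at 12 h (-0.06 and 0.05) and 16 h (-0.04 and 0.10), given as median and mean.

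**Figure D2:**
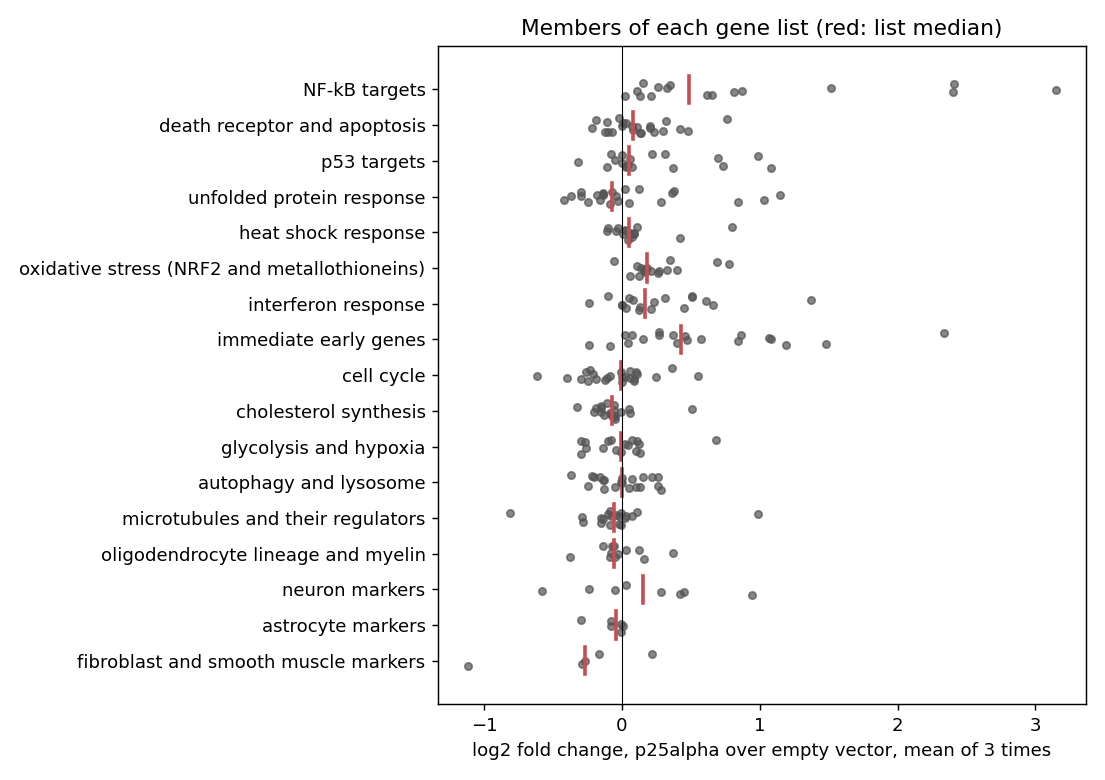
Log2 fold change of p25alpha over mock cells, averaged over the 3 times, for each measured member (grey points) of the 17 gene lists tested, with each list's median as a red bar. The NF-kB targets and immediate early genes have medians of 0.49 and 0.43, and the cholesterol list has a median of -0.07.

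At 8 h, the earliest time, 0 probe sets passed in limma without the block and 0 in the paired fit, with 210 and 940 at an unadjusted p under 0.05. Chance alone would give 962, so the paired count was not above it. The transcripts with the smallest p included those of the pooled comparison. Cxcl1 was at 11-fold (log2 3.46 ± 0.64 SE, adjusted p = 1), Egr1 at 3.59-fold (log2 1.84 ± 0.24, adjusted p = 0.491), Il6 at 3.28-fold (log2 1.71 ± 0.32) and Nsmce3 at 2.26-fold (log2 1.18 ± 0.29), each higher in 2 of 2 pairs. Over all times this Nsmce3 probe set passed in the paired fit (0.97, adjusted p = 0.0263) while another measured -0.17 (adjusted p = 0.324). LOC310926 was 9.47-fold higher, set against signals called absent on both mock arrays. On the lower side Id4, an inhibitor of differentiation, was at -0.62 ± 0.20, Taok1 at -0.61 ± 0.21 and Adgrl2 at -0.78 ± 0.29, and none passed. The other Id4 probe sets measured 0.25, 0.34 and -0.11, and another Adgrl2 probe set measured -0.22. On the 2 mock arrays at 8 h the signals were 151.6 and 138 for Id4 and 275.4 and 242.9 for Taok1. These were above every other array, later mock arrays included, so the lower values may reflect those 2 arrays. The immediate early list (median 0.34, adjusted p = 4.88e-14, adjusted p = 0.0411 with an estimated correlation, and adjusted p = 0.0765 with one in the paired fit) and the NF-kB list (median 0.44, adjusted p = 1.02e-08, adjusted p = 0.137 with an estimated correlation) were shifted upwards. So were the oxidative stress (median 0.18) and interferon (median 0.17) lists, both with adjusted p = 0.137 with an estimated correlation. In the immediate early list 4 genes, and in the NF-kB list 3, rose when adjusted over the list alone without the block, against 6 and 5 in the paired fit and 0 over all genes in both fits. Leaving out mock 8 h replicate 1 or p25alpha 8 h replicate 1 gave 1 probe set call each, and without these arrays or p25alpha 8 h replicate 2 only 2 lists were called.

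At 12 h, Egr1 was 6.42-fold higher in p25alpha than in mock cells (log2 2.68 ± 0.24 SE, 2 of 2 pairs, limma adjusted p = 0.0345). From 8 to 12 h its mean signal went from 332.7 to 392.3 in p25alpha cells and from 93.4 to 61.3 in mock cells. The unnamed probe set of the pooled comparison was also higher at 12 h, and these were the only 2 to pass without the block. There were 475 at an unadjusted p under 0.05. Egr1 lost its call without any single array other than the p25alpha arrays at 16 h (adjusted p from 0.0785 to 0.285) and without a filter on dim probe sets (adjusted p = 0.103), and the count was 4 without either of those and 0 or 1 without any of the others. With the block it was 2 without either mock array at 8 h, 0 without mock 12 h replicate 1, and 3 to 7 without either p25alpha array at 8 h, either p25alpha array at 12 h or mock 12 h replicate 2. The paired fit called 10 higher and 1 lower. The rises it added included Cxcl1 (8.09-fold), Il6 (6.75-fold), Ccl2 (6.54-fold) and Txnip. The 4.92-fold of Txnip (adjusted p = 0.0334 paired, 0.878 without the block) is set against signals called absent on both mock arrays. Klf10, at 2.61-fold, did not pass in either fit (adjusted p = 0.878, and 0.245 paired). Lower values that did not pass were those of Mcm6 (-0.91 ± 0.12 paired), Arfgap3 (-0.85 ± 0.13), Arsb (-0.78 ± 0.16) and Lrrc42 (-0.73 ± 0.14). Another Arsb probe set was at -0.26. The NF-kB (median 0.50), immediate early (median 0.47) and interferon (median 0.32) lists were shifted upwards, with adjusted p = 0.169, adjusted p = 0.0897 and adjusted p = 0.169 with an estimated correlation. Of their members 3, 7 and 0 rose when adjusted over the list alone without the block and 6, 11 and 0 in the paired fit, against 0, 1 and 0 and then 3, 1 and 0 over all genes. The oxidative stress list (median 0.20) was called in the paired fit only (adjusted p = 0.00312 paired and 0.228 without the block, adjusted p = 0.439 with an estimated correlation in the paired fit). Without mock 12 h replicate 1 or p25alpha 12 h replicate 2 only 2 lists were called.

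At 16 h, 0 probe sets passed without the block and 463 had an unadjusted p under 0.05, while the paired fit called 10 higher and 1 lower. In the paired fit Il6 rose 6.71-fold, Cxcl1 7.89-fold, Gadd45b 5.61-fold and Egr1 5.59-fold, and Txnip was 5.21-fold higher than mock signals called absent. Their adjusted p in that fit were between 0.0199 and 0.0437, and without the block the smallest was 0.0628, for Egr1. Leaving out p25alpha 16 h replicate 2, the array with the highest median signal (35.3) and the fewest present calls (49.3%), gave 7 calls without the block and 30 in the paired fit. Leaving out mock 16 h replicate 2 gave 4 and 20, and in the paired fit leaving out either p25alpha array at 8 h gave 5 and any of the remaining 8 arrays gave 0 or 1. Gadd45g was at 3.76-fold and did not pass in either fit. Among the lower transcripts with the smallest p were Prpf4b (-0.95 ± 0.23), Snrnp200 (-0.69 ± 0.18) and Pld1 (-0.88 ± 0.24), none of them past the threshold in either fit. Other probe sets measured 0.00 and 0.10 for Prpf4b and 0.09, -0.32 and 0.11 for Pld1. Upward shifts were found for the NF-kB (median 0.53), immediate early (0.49), oxidative stress (0.25) and p53 target (0.24) lists, each with adjusted p = 0.0505 with an estimated correlation. In the p53 list 5 genes, among them Bbc3 and Mdm2, passed in the paired fit and 2 without the block when adjusted over the list alone, and 0 over all genes in both fits. The counts in the NF-kB, immediate early and oxidative stress lists were 5, 10 and 1 in that fit and 2, 6 and 0 without the block, against 2, 1 and 0 and then 0 in each over all genes. The cholesterol synthesis list was shifted downwards, with 19 of 20 genes lower and a median of -0.24 (adjusted p = 0.00224, adjusted p = 0.336 with an estimated correlation). The microtubule list (median -0.07) was called in the paired fit only (adjusted p = 0.0464 paired and 0.113 without the block, adjusted p = 0.195 with an estimated correlation in the paired fit). Without p25alpha 16 h replicate 1 only 2 lists were called.

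Whether the p25alpha effect differed between times was tested directly with a limma F-test. No probe set passed in either fit, so no transcript is described here as specific to a time. There were 192 at an unadjusted p under 0.05 without the block and 763 in the paired fit, where chance alone would give 962. Mdm2, which encodes the ubiquitin ligase of p53, had a log2 effect 1.06 ± 0.35 larger at 16 h than at 8 h, and Klf10 one 0.88 ± 0.40 larger, both with adjusted p = 1. In the paired fit the log2 effect at 16 h minus that at 8 h was 1.17 ± 0.25 for Gadd45b, 1.54 ± 0.31 for Oga and -0.90 ± 0.18 for Stx5, all with adjusted p = 0.999. The other Oga probe sets had effects of -0.13 and -0.66 at 8 h and 0.38 and 0.40 at 16 h. Of the other Stx5 probe sets, one had 0.33 at 8 h and -0.06 at 16 h, and another went the other way, with -0.98 and -0.04.

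In mock cells, transcripts of cholesterol synthesis were higher at later times. Tm7sf2, a sterol reductase gene, was at 3.90-fold at 16 h against 8 h (log2 1.96 ± 0.18 SE in the paired fit, adjusted p = 0.0857), Nsdhl at 2.75-fold (1.46 ± 0.13) and Fdps at 2.66-fold (1.41 ± 0.12), all 2 of 2 pairs higher. Over all genes 0 probe sets passed in either fit, with 339 at an unadjusted p under 0.05 without the block and 1425 in the paired fit. Of the 20 list members 19 were higher at 16 h, with a median of 1.06 on the log2 scale. The camera test of the list at this contrast, added after these genes were seen, gave adjusted p = 1.87e-34, adjusted p = 0.0141 with an estimated correlation, and adjusted p = 0.179 with an estimated correlation in the paired fit. Adjusted over the list alone, 11 of the 20 passed without the block and 18 in the paired fit, all higher at 16 h. Over the same interval the actin 3′ over 5′ ratio went from 2.14 to 2.60 in experiment 1 and from 4.65 to 7.05 in experiment 2. Id4 at -0.99 ± 0.20 and Il1rl1, an interleukin 33 receptor gene, at -0.87 ± 0.23 had the lowest p among the lower transcripts and did not pass, and other Id4 probe sets measured 0.27, 0.21 and -0.25. The Id4 value has the same 2 mock arrays at 8 h as its baseline as the lower Id4 value in p25alpha cells at 8 h. At 12 h against 8 h, Tm7sf2 was at 1.91-fold and Nsdhl at 1.78-fold, and 0 probe sets passed without the block, with 252 at an unadjusted p under 0.05. The list median was 0.52 (adjusted p = 1.65e-18, adjusted p = 0.0705 with an estimated correlation), and adjusted over the list alone 0 members passed without the block and 10 in the paired fit. Leaving out mock 8 h replicate 1 gave 1 call in each of the 2 contrasts, and leaving out mock 12 h replicate 2 gave 1 at 12 h. The paired fit called 1 at 12 h, Ppm1k, a mitochondrial phosphatase gene. It was absent on both mock arrays at 12 h, so its fitted log2 value of -4.26 (adjusted p = 0.00726 paired and 0.0797 without the block) is not a measured size, and it lies outside the naming rule and was singled out after its value was seen.

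**Figure D3:**
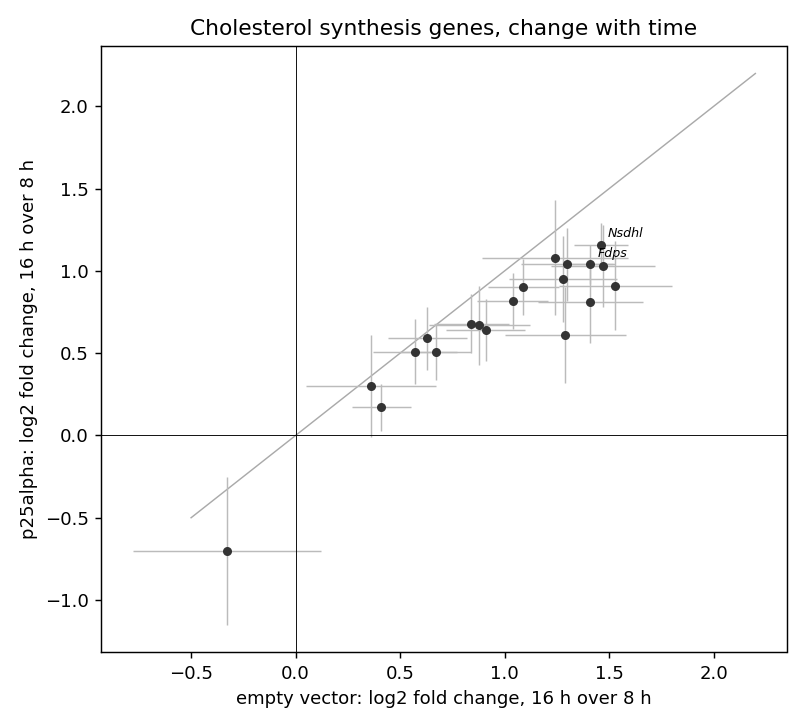
Log2 fold change at 16 h over 8 h of the 20 measured cholesterol synthesis genes in mock cells (horizontal axis) and in p25alpha cells (vertical axis), with SE from the paired fit as bars and the line of equal change in grey. In both arms 19 of 20 genes lie above 0, with medians of 1.06 in mock and 0.75 in p25alpha cells.

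The authors' deposited table also holds MAS5 calls for each p25alpha array against the mock array of its own time and experiment. There were 20 probe sets called increased in 6 of 6 comparisons in the authors' deposited table, 1 of them an array control, and 0 were called decreased in all 6. These included Cxcl1 with signal log ratios of 2.8 to 3.7, Ccl2 with 1.7 to 3.1, Il6 with 1.5 to 3.3 and Nfkbia with 1.3 to 1.7 in the authors' deposited table. Both experiments were called increased for 43 probe sets at 8 h, 130 at 12 h and 117 at 16 h, and decreased for 9, 69 and 77, in the authors' deposited table. The experiments were called in opposite directions for 14, 2 and 2 probe sets at these times in the authors' deposited table.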

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

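The control probe sets of the array, which the comparisons above leave out, were compared between arms only after the authors' change calls had been seen. The 5S ribosomal RNA control had a mean signal of 43.1 ± 5.2 (SD, n = 6) on the mock arrays and 249.9 ± 159.8 on the p25alpha arrays. It was higher in 6 of 6 pairs, by 2.31 ± 0.96 on the log2 scale (exact sign-flip permutation test, two-sided, p = 0.0312, the smallest that 6 pairs allow, adjusted p = 0.203 over the 52 controls present on all arrays). In the authors' deposited table this control was called increased in 6 of 6 comparisons. A further 6 controls were higher in 6 of 6 pairs by smaller amounts, with the same p and adjusted p in the exact test. These were GAPDH 5′ (0.09), LysX-M (0.44), PheX-3 (0.15), r2-Bs-phe-3 (0.37), r2-Bs-thr-5 (0.46) and r2-Bs-thr-M (0.38). All but GAPDH belong to the Dap, Lys, Phe and Thr controls, whose labels name no rat gene. Every control of these 4 names was higher on average, from 0.14 for r2-Bs-lys-M to 0.56 for ThrX-5, though not each in all pairs. The cause of this shift between the arms was not tested. BioC-3 was lower in 6 of 6 pairs (-0.46 ± 0.65, from -1.73 to -0.03). Other bioC controls did not share this, r2-Ec-bioC-3 (0.18 ± 0.19) and r2-Ec-bioC-5 (0.16 ± 0.27) being higher in 5 of 6 pairs. BioC-5 was at -0.37 ± 0.92 and higher in 3 of 6 pairs.

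The effect of p25alpha on the cholesterol synthesis list differed between 16 h and 8 h, by a median of -0.25 on the log2 scale over 20 genes (camera adjusted p = 0.00638 over 17 lists, adjusted p = 0.553 with an estimated correlation, adjusted p = 0.00378 in the paired fit). This test was added after seeing the data.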

How the results depend on the processing

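The paired fit as a result of its own, its version with trend and robust, the actin covariate and the block with an estimated correlation were chosen after seeing the data, and all other alternatives before. The number of probe sets called depended on the model. Il6 and Egr1 over all times stayed past the threshold in all 21 alternatives, at 1.68 to 2.53 and 1.73 to 2.40 on the log2 scale. Of 135 named probe sets, 0 to 2 changed sign in a setting that kept all arrays and 5 to 13 when an array was left out, 0 of them in a called value. Quantile normalization or median centring left the median of all probe sets at 0.031 or closer to 0. Of the 46 paired calls, 35 were also called after quantile normalization, 39 after median centring and 11 to 23 when an array was left out, with 46 of 46 in the same direction. Without a filter more probe sets were tested, which raises adjusted p by construction, and leaving out arrays or adding a covariate leaves fewer residual degrees of freedom. For the other changes of count the cause was not tested. Signal over background limits the dim probe sets, since 49.3% to 55.2% were called present per array.

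With the replicate block the counts went from 4 to 46 over all times, from 2 to 11 at 12 h, from 0 to 11 at 16 h and from 0 to 1 for mock cells at 12 h against 8 h. As a random replicate block the experiment gave 45, 11, 9 and 1, and 2 for mock cells at 16 h against 8 h. The block with trend and robust gave 419 over all times, 10 at 8 h, 57 at 12 h, 64 at 16 h, and 4 and 65 for mock cells at 12 and 16 h. For the effect of p25alpha, camera with the preset correlation changed no list call with the block other than those given beside the results. Calls by fry did change with the block, among them the NF-kB targets at 8 h (adjusted p = 0.418 without and 0.0215 with it) and the interferon list over all times (adjusted p = 0.116 and 0.00416).

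Without the block, quantile normalization gave 4 at 12 h, 2 at 16 h and 1 for mock cells at 12 h. The filter at the median signal gave 7 over all times, 4 at 12 h and 2 at 16 h. The offset of 50 gave 3 at 12 h, 3 at 16 h and 1 for mock cells at 16 h, and trend and robust gave 3 and 2 at 12 and 16 h. At 12 h the count was 0 without a filter and 0 with only the 4 arrays compared.

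In the paired fit the counts over all times, at 12 h and at 16 h were 46, 11 and 11. They were 17, 0 and 0 without a filter, 141, 18 and 23 with the filter at the median signal, 466, 59 and 75 with the offset, 419, 57 and 64 with trend and robust, 17, 0 and 0 with the actin covariate, and 4, 2 and 0 with no replicate block.

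Of the shifted lists, 4 at 8 h, 3 at 12 h, 5 at 16 h and 5 over all times, an estimated correlation left 1, 0, 0 and 1, and the block with an estimated correlation 0 in each. Tested with fry, which does not compare a list with other genes, 1, 1, 1 and 4 passed in one direction at the single times and over all times, and 2, 2, 2 and 3 in either direction. At 12 h 2 lists were called without a filter and 5 with the filter at the median signal.

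When each array was left out in turn, the counts ranged from 3 to 5 over all times, 0 to 1 at 8 h, 0 to 4 at 12 h, 0 to 7 at 16 h, 0 to 0 for time dependence, and 0 to 1 in both comparisons of mock cells. Those of the paired fit ranged from 12 to 33 over all times, 0 to 10 at 12 h and 0 to 30 at 16 h. The lists ranged from 2 to 4 at 8 h, 2 to 3 at 12 h, 2 to 6 at 16 h and 4 to 7 over all times.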

Other observations

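The tests of array scaling and RNA quality on the p25alpha rises, the comparison of Fkbp2 probe sets and the look at the p25alpha arrays for the cholesterol list were chosen after the results were seen. The splits and the scaling and RNA quality tests of the cholesterol list were written down before their results were seen.

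In mock cells 15 of 17 glycolysis and hypoxia genes were higher at 16 h than at 8 h, with a median of 0.25 on the log2 scale, in a list test added after seeing the data (camera adjusted p = 8.05e-06, adjusted p = 0.0158 with an estimated correlation, and the call was lost with an estimated correlation in the paired fit, adjusted p = 0.0801). Over all genes 0 of the 17 passed in either fit, and adjusted over the list alone 0 passed without the block and 1 in the paired fit, Bnip3 (0.77 ± 0.14, adjusted p = 0.0126), singled out after its value was seen. In p25alpha cells 11 of the 17 were higher, with a median of 0.08 and 0 past the threshold (adjusted p = 0.0549, and 0.0456 in the paired fit). With an estimated correlation the list did not pass there (adjusted p = 0.277, and adjusted p = 0.279 in the paired fit). The 24 cell cycle genes had medians of -0.20 in mock cells (adjusted p = 0.0431, adjusted p = 0.544 with an estimated correlation, and adjusted p = 0.462 with one in the paired fit) and -0.29 in p25alpha cells (adjusted p = 0.00166, then 0.431 and 0.279). Over all genes 0 of them passed in either fit. Adjusted over the list alone 0 passed without the block, and in the paired fit 3 were lower in mock cells (Birc5, Cdc20 and Plk1) and 4 in p25alpha cells (Aurka, Birc5, Cdk1 and Ube2c), also singled out afterwards. The difference between the arms was not past the threshold for either list (adjusted p = 0.17 and adjusted p = 0.698).

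The rise of 40 probe sets in p25alpha cells in the paired fit could be an effect of p25alpha or a technical difference between the arms. Of the 32 array splits that part all 6 pairs, 1, the real one, gave as many as 4 calls without the block (highest other 1). In the paired fit, again only the real one gave as many as 46 (highest other 2). No stronger outcome is possible with 32 splits, and the 6 pairs come from 2 experiments and may not be independent. These counts therefore argue against chance without excluding it. The 40 probe sets had a median of 1.15 on the log2 scale, which was 1.07 after quantile normalization and 1.15 with the actin ratio as a covariate, all 40 above 0 in both, and with the covariate 15 of the 40 passed, their median SE staying at 0.12 while the residual degrees of freedom fell to 4. Between the arms the median signal differed by 0.11 ± 0.10 on the log2 scale (SD). The log2 actin ratio differed by 0.05 ± 0.16 and was higher in p25alpha in 4 of 6 pairs. With arms this close, the normalization and the covariate could hardly have changed a rise of this size, so their results alone decide little. The small difference of the actin ratio argues against the RNA quality that it measures as the whole cause. The median signals were compared after scaling to a trimmed mean of 150.1, so they do not show how the arms differed before it. Any common shift left in the deposited signals was small, the median effect over all tested probe sets being 0.013. Other differences between arrays stay open, since the p25alpha array had a higher median signal in 6 of 6 pairs and fewer present calls in 5 of 6. The 5S ribosomal RNA control was also higher in 6 of 6 pairs (2.31 ± 0.96), and every Dap, Lys, Phe and Thr control was higher on average. Any other difference between the plasmid transfections stays open too, because the design has no control for it.

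Of the same 32 splits, 3 gave as many as the 5 shifted lists, the real one included (highest other 5). The others turned only 1 of the 6 pairs, that is exchanged its mock and p25alpha arrays, in experiment 2 at 12 h or at 16 h. They keep most of the real difference between the arms. The number of lists therefore neither excludes chance nor shows that chance gives as many. For a single list, the real split is the largest of the 32 whenever all 6 pairs share a sign. The highest other value is then the real one with 1 pair turned, so it is not a chance level. In 6 lists the mean over members was higher in p25alpha cells in 6 of 6 pairs, so the real split was the largest. These were the NF-kB targets (0.87, highest other 0.77), the immediate early genes (0.58, highest other 0.42), the oxidative stress list (0.26, highest other 0.20), the p53 targets (0.23, highest other 0.18), the death receptor list (0.12, highest other 0.12 after rounding) and the unfolded protein response (0.07, highest other 0.06), each with exact p = 0.0312, the smallest that 32 splits allow, and adjusted p = 0.0884 over 17 lists. In the unfolded protein response list 14 of 23 genes were lower over all times, with a median of -0.07, so its positive mean is not a rise of most members. The interferon list, also among the 5 shifted lists, was exceeded by another split (0.27, highest other 0.30, higher in 5 of 6 pairs, exact p = 0.0625, adjusted p = 0.133). Among 68 other splits drawn, which do not part all pairs, the highest count without the block was 9799, which points to the difference between the experiments.

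One of 3 Fkbp2 probe sets, present on 10 of 12 arrays, was 2.91 ± 0.16 higher in p25alpha cells on the log2 scale. The higher of the other Fkbp2 probe sets measured 0.12 ± 0.09, which argues against a rise of the Fkbp2 transcript as a whole. Its signal may come from another transcript or from a changed transcript end, and the probe sequences needed to tell these apart were not used here.

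Cholesterol synthesis transcripts were higher at 16 h than at 8 h in mock cells, by a median of 1.06 on the log2 scale over 20 genes. The median was 0.98 after quantile normalization and 0.75 in the p25alpha arrays, with 19 of 20 genes above 0, which argues against array scaling and against chance in the 4 mock arrays. With the actin ratio as a covariate it was 0.73, with a median SE of 0.38. RNA quality as the actin ratio measures it therefore cannot be told apart as a partial cause, because that ratio moved with time in both experiments. The GAPDH 3′ over 5′ ratio of the mock arrays had no common direction. From 8 to 16 h it went from 1.09 to 1.05 in experiment 1 and from 0.92 to 1.03 in experiment 2. That the cells raise sterol synthesis with time after transfection stays a hypothesis, since untransfected cells were not analysed here.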
